A study of Homo sapiens with 6 samples.

How the data were processed

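Gene expression was measured on 6 Affymetrix arrays, each hybridised with biotin-labelled cRNA from THP-1 macrophages. THP-1 is an established human monocytic leukaemia cell line, and the phorbol ester PMA turns its cells into adherent macrophages. Per the labels' protocols, the cells received 100 nM PMA for 72 hours and were then incubated for 18 hours with human lipoproteins that had been treated with heparin-containing medium of HEK-293T cells, a human embryonic kidney line. In 3 samples that medium came from cells expressing human lipoprotein lipase (LPL), the enzyme that releases fatty acids from lipoprotein triglyceride, and in the other 3 samples it came from control cells. The unesterified fatty acid content was 0.68 mM in the first group and 0.03 mM in the second. Per the labels, RNA was extracted with TRIzol, treated with DNase and cleaned on a spin column, and 250 ng was labelled.

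The deposited table holds log2 expression values made by the authors with RMA (background correction, quantile normalisation and summary per probe set), and the submitters' processing notes name oligo 1.32.0 and R 3.2.0. The level of summarisation, any filter and the genome build are not given in the sources used here, so no genomic coordinates are printed. The table has 53617 probe set rows with values from 0.614 to 13.7 and no pooled columns. RMA values carry no count of reads and no detection call, so the number of arrays is what limits the precision, and a low value cannot be told from background by the table itself. RMA also compresses differences near the low end of the scale.

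Rows were named through the platform annotation, which paired 16098 rows with 1 gene symbol and none with several. The other 37519 rows are unnamed here and entered only the fit on all rows. All 16098 gene identifiers matched the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. The named rows covered 14884 genes, of which 11916 are protein coding, 1398 are long non-coding RNAs and 1072 are microRNAs. For the 779 genes with several rows, the row with the highest mean over all 6 arrays was used. Many members of the gene lists were not named by this annotation and are not analysed here, among them PDK4, FABP4, ABCA1, ABCG1 and IL1B.

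Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over the 14884 genes and a threshold of 0.05. All adjusted p-values of single genes come from this limma fit. Changes are log2 differences, hydrolysis products minus control, given with limma's moderated standard error (SE), and levels are means ± SD. A total of 30 gene lists was fixed before the data were examined, and the 28 lists with at least 5 measured genes were tested with camera at its preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, were run beside it, each adjusted over the 28 lists. Genes named in the text were chosen by a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls among called genes whose 3 values in each group did not overlap, without small RNAs, microRNAs and uncharacterised symbols. It also took up to 4 members with the smallest p of each list, and a set of lipid and cytokine genes whatever their values. Genes named outside this rule are marked as such. A further 7 gene groups chosen after seeing the data were adjusted over those 7 and also together with the 28 lists, over 35.

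On simulated data modelled on these arrays, with 66 or 67 changed genes of each size among 14884, the limma fit recovered 22.7% of changes of 0.5 on the log2 scale, 88.1% of changes of 1 and 94.0% of changes of 1.5, with 7 false calls. In a simulation with 1 list lowered by 0.5 on the log2 scale, camera called that list and 0 of the others. The simulated genes varied independently, so this run could not test the preset correlation. The replicate numbers were not taken to pair the samples. The alternatives run were a replicate block, other empirical Bayes settings, array weights, filters on dim genes, 3 further normalisations, other row choices, other thresholds and leaving out each array. The labels do not say whether the samples came from separate cultures, so p-values measure the spread between these samples, which may be technical. No batch or scan date is given. With 3 arrays against 3, a permutation test of a single value cannot go below 0.1, so none was run.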

Results

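The series asked which transcripts of human macrophages differ after exposure to the products that LPL releases from lipoproteins. The 6 arrays form 2 groups of 3, macrophages given lipoproteins hydrolysed by LPL (0.68 mM unesterified fatty acid) and macrophages given lipoproteins treated with control medium (0.03 mM). The array medians over all rows lay between 4.51 and 4.63 on the log2 scale. The first principal component, with 45.2% of the variance, separated the groups. The second, with 20.1%, set replicate 3 of the hydrolysis product group apart from its own group. That array correlated at 0.976 with each of its group's other arrays, which correlated at 0.985 with each other, and its limma array weight of 0.49 was the lowest of the 6.

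**Figure D1:**
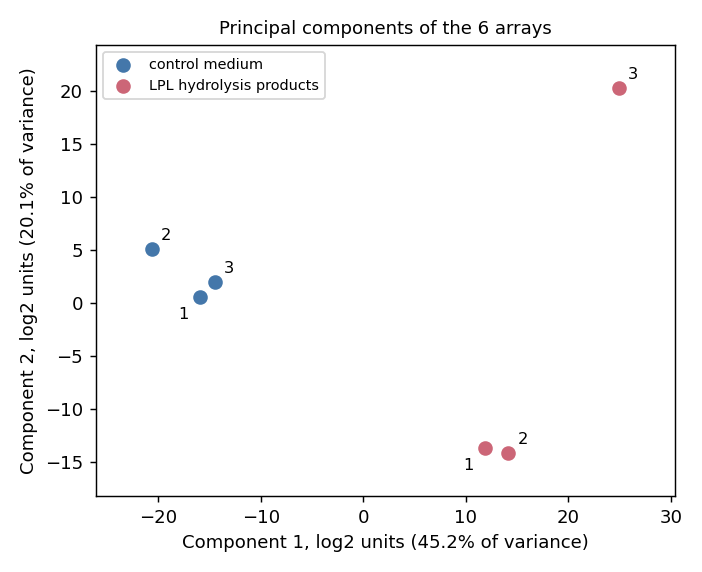
Principal components 1 and 2 of the 14884 named genes for the 6 arrays, in log2 units, with points coloured by group and numbered by replicate. The groups part along component 1 (45.2% of the variance), and replicate 3 of the hydrolysis product group lies apart from its group along component 2 (20.1%).

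Of 14884 genes tested, 270 were higher and 421 lower with hydrolysis products at an adjusted p under 0.05. Of these, 41 rose and 87 fell at least 2-fold. The values of the groups did not overlap for any of the 691 called genes, and over all genes tested they did not overlap for 27.6%, where chance gives 10%. The largest rises were in HSPA1A (5.98-fold, log2 change 2.58 ± 0.18 SE, adjusted p = 0.00171) and HSPA1B (5.61-fold, 2.49 ± 0.15, adjusted p = 0.0016), the inducible HSP70 chaperones, whose near-identical sequences mean that their probe sets may read the same transcripts. The largest measured fall was in the interferon-induced gene IFI44L (10.6-fold on the measured values, log2 change -3.40 ± 0.27, adjusted p = 0.00224), from a level of 7.63 ± 0.35 to 4.23 ± 0.51 (SD, n = 3 each). The lower level lay under 6.28, the 95th percentile of 85 genes of families that macrophages should lack, a reference chosen after results were seen, so the true size of this fold is not known. Centring each array on its median gave 356 higher and 309 lower, which changed the share of called genes that were lower from 60.9% to 46.5%. Leaving out the array that stood apart, replicate 3 of the hydrolysis product group, left 143 genes higher and 290 lower. Leaving out control replicate 1 left 58 and 117.

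The other large rises included 3 genes of fatty acid handling. CPT1A, the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, rose 3.02-fold, the fatty acid and oxidised lipoprotein receptor CD36 rose 2.95-fold, and the lipid droplet coat protein PLIN2 rose 2.93-fold. The remaining 7 were the cytokine IL24 (3.48-fold), the cannabinoid receptor CNR1 (3.32-fold), the glucocorticoid-inducible annexin ANXA1 (3.13-fold), the stress transcription factor ATF3 (2.95-fold), the tight junction protein OCLN (2.79-fold), thrombomodulin (THBD, 2.57-fold) and the neutrophil chemokine CXCL5 (2.51-fold). Among the falls, the interferon-induced genes CXCL10 (4.53-fold), IFITM1 (4.52-fold) and IFI44 (3.03-fold) stood beside the chemokines CCL1 (3.51-fold) and CCL19 (2.90-fold), the alarmin IL33 (3.09-fold) and macrophage elastase MMP12 (3.07-fold). IFITM1 has close paralogs that its probes may share. DTL, a replication-coupled ubiquitin ligase adaptor, fell 3.22-fold and the kinetochore gene SKA1 3.02-fold, and the Wnt regulator DKK2 (3.89-fold) and HMSD (3.60-fold) also fell. All 24 had adjusted p-values between 0.0016 and 0.0155. Of the 24, 9 had 1 group mean under the level of 6.28 and OCLN and SKA1 had both, so the sizes of these folds are uncertain. Among the 74 called genes taken by the naming rule, 16 had 1 group mean under that level and 5 had both (OCLN, SKA1, MX2, CD86 and AIM2). Outside the 24, those with 1 were FADS2, CRELD2, CCNA2, RRM2, TLR7, MYB and MERTK. The sizes of these changes, given below, are uncertain too, as are those of MX2, CD86 and AIM2. With 1 array left out, 19 of the 24 passed in all 6 fits. The exceptions were CXCL5 and IL33 (adjusted p = 0.0588 each without control replicate 1), IFI44 (0.0608 without control replicate 1), CCL19 (0.0735 without control replicate 2) and MMP12 (0.0775 without control replicate 2).

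**Figure D2:**
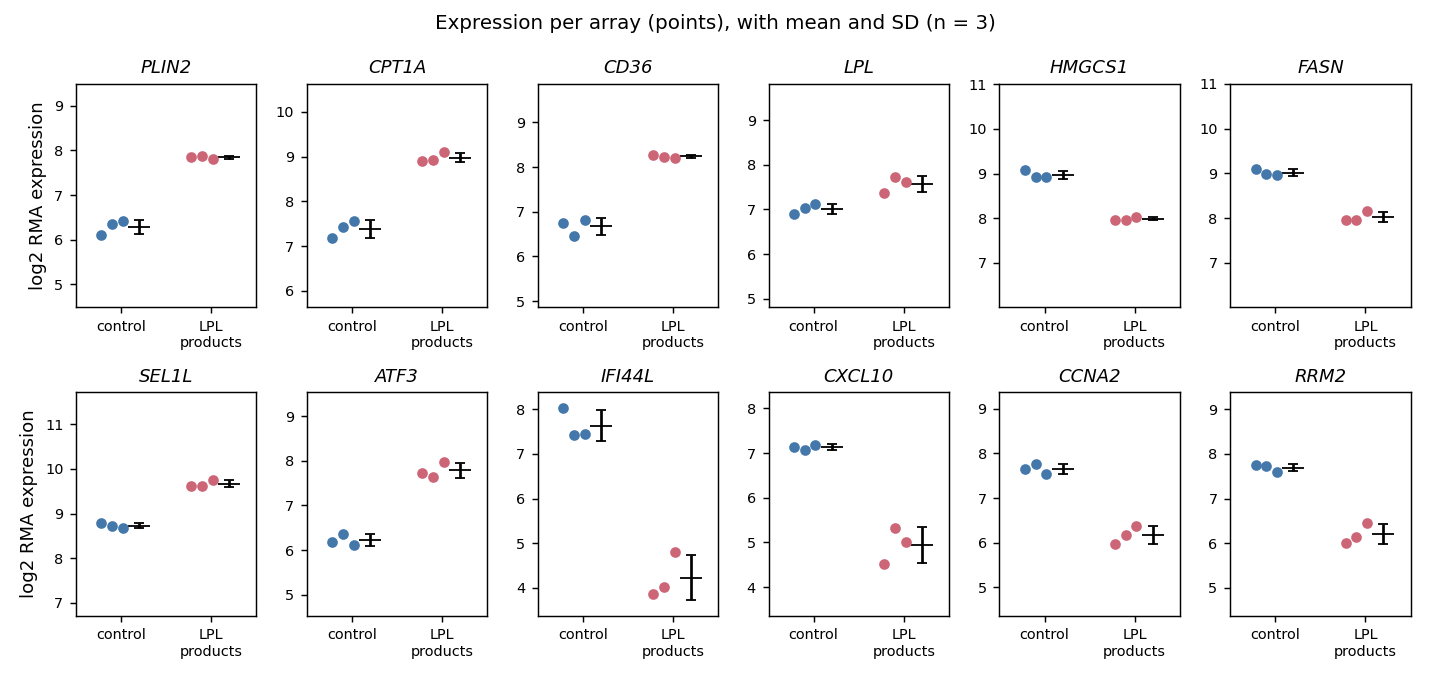
Log2 RMA expression of 12 genes on each of the 6 arrays, with the mean and SD of each group (n = 3) beside the points and 5 log2 units on every vertical axis. PLIN2, CPT1A, CD36, LPL, SEL1L and ATF3 were higher with hydrolysis products in all 3 arrays, and HMGCS1, FASN, IFI44L, CXCL10, CCNA2 and RRM2 were lower.

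Of the 12 measured target genes of PPARs, the fatty acid-sensing nuclear receptors, 5 rose, 1 fell and 6 did not pass. PLIN2 rose from 6.30 ± 0.16 to 7.85 ± 0.03 (SD, n = 3 each; log2 change 1.55 ± 0.10, adjusted p = 0.00171), CD36 rose by 1.56 ± 0.11 (adjusted p = 0.00171) and CPT1A went from 7.38 ± 0.19 to 8.98 ± 0.10 (adjusted p = 0.00195). The delta-5 desaturase FADS1 fell by 0.73 ± 0.08 (adjusted p = 0.0061). ANGPTL4, a secreted LPL inhibitor, had a change of 0.63 ± 0.17 that did not pass (adjusted p = 0.0849). The list rose in the camera test (median log2 change 0.31, adjusted p = 0.00235), with adjusted p = 0.133 with an estimated correlation. Its lower quartile was -0.03, so the rise was uneven over its members. Adjusted over the list alone, 6 members rose and 1 fell. CPT1A, PLIN2 and CD36 are also members of the oxidation, lipid droplet and uptake lists below, so the calls of these lists are not independent. Whether the calls hold without these genes was not tested.

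Of 9 measured genes of fatty acid oxidation, 4 rose and 5 did not pass. Besides CPT1A these were the peroxisomal enzyme HSD17B4 (0.66 ± 0.10, adjusted p = 0.0149), the mitochondrial thiolase ACAA2 (0.52 ± 0.10, adjusted p = 0.035) and the electron carrier ETFDH (0.51 ± 0.11, adjusted p = 0.0429). For this list the median was 0.32 (camera adjusted p = 0.0057, and adjusted p = 0.225 with an estimated correlation). Adjusted over the list alone, 5 rose and 1 fell. Of 18 genes of triglyceride synthesis and lipid droplets, only PLIN2 and the cholesterol acyltransferase SOAT1 (0.41 ± 0.08, adjusted p = 0.0382) rose, also when adjusted over the list alone. G0S2, an inhibitor of triglyceride lipase (0.35 ± 0.11, adjusted p = 0.141), and its lipase coactivator ABHD5 (0.24 ± 0.10, adjusted p = 0.235) did not pass. This list's median was 0.07 (camera adjusted p = 0.0243, and adjusted p = 0.18 with an estimated correlation), and it was 0.13 without hydrolysis product replicate 2 and 0.12 with each array centred. The camera call ended without replicate 3 of the hydrolysis product group (adjusted p = 0.104), where 2 oxidation genes and 1 lipid droplet gene were called. Among genes at or above the median level the calls of both lists ended (medians 0.24 and 0.10, adjusted p = 0.0681 for oxidation and 0.071 for lipid droplets). Above the 75th percentile of level both lists passed (medians 0.51 and 0.17, adjusted p = 0.0193 each). HSD17B4, ACAA2, ETFDH and SOAT1 lost their calls in at least 4 of the 6 fits that left out 1 array, with highest adjusted p-values of 0.0588 and 0.117 without control replicate 1, 0.141 without control replicate 3 and 0.124 without hydrolysis product replicate 2.

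Of 12 genes of lipoprotein and fatty acid uptake, 2 rose, CD36 and LPL itself, and 4 rose when adjusted over the list alone. LPL transcript went from 7.01 ± 0.12 to 7.56 ± 0.18 (SD, n = 3 each), 1.47-fold (log2 change 0.55 ± 0.12, adjusted p = 0.046). This call passed in 1 of the 6 fits with an array left out (highest adjusted p = 0.141, without control replicate 1) and in 2 of 3 further normalisations. The scavenger receptors OLR1 (0.79 ± 0.18, adjusted p = 0.054) and MSR1 (0.70 ± 0.16, adjusted p = 0.0601) did not pass. The uptake list had a median of 0.24 (camera adjusted p = 0.00583, and adjusted p = 0.146 with an estimated correlation), and 1 member was called without replicate 3 of the hydrolysis product group. None of the 5 measured LXR target and cholesterol efflux genes passed, with changes of 0.35 ± 0.11 for APOE and -0.28 ± 0.11 for MYLIP. As a list they did not pass (camera adjusted p = 0.932).

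Of 17 measured genes of cholesterol biosynthesis and other SREBP-2 targets, 10 fell, none rose and 7 did not pass, with 15 lower when adjusted over the list alone. The last enzyme of the pathway, DHCR7, fell by 1.19 ± 0.09 on the log2 scale (adjusted p = 0.00198), HMGCS1, the HMG-CoA synthase, by 0.98 ± 0.09 (adjusted p = 0.00276), the farnesyl diphosphate synthase FDPS by 0.94 ± 0.09 (adjusted p = 0.00333) and the acetoacetyl-CoA thiolase ACAT2 by 1.03 ± 0.10 (adjusted p = 0.00384). Over the list the median was -0.51 (camera adjusted p = 9.33e-12). It was the only list past the threshold with an estimated correlation (adjusted p = 0.0432), a call that ended when 7 groups chosen after results were seen were adjusted with the 28 lists (adjusted p = 0.0539). Of 18 genes of fatty acid synthesis and desaturation, 8 fell and 10 did not pass, with the same count of 8 adjusted over the list alone. Fatty acid synthase (FASN) fell by 0.99 ± 0.10 (adjusted p = 0.0036), the delta-6 desaturase FADS2 by 1.05 ± 0.11 (adjusted p = 0.0043), FADS1 by 0.73 ± 0.08 and acetyl-CoA carboxylase (ACACA) by 0.71 ± 0.09 (adjusted p = 0.00732). The stearoyl-CoA desaturase SCD fell by 0.49 ± 0.10 (adjusted p = 0.0441), a call lost under each of 3 further normalisations and in every fit that left out 1 array (highest adjusted p = 0.144, without control replicate 2). The fatty acid synthesis list had a median of -0.25 (camera adjusted p = 5.4e-06, and adjusted p = 0.133 with an estimated correlation).

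Of 11 genes of the endoplasmic reticulum unfolded protein response, 6 rose and 5 did not pass, and adjusted over the list alone 8 rose and 1 fell. SEL1L, an adaptor of ER-associated degradation, rose by 0.94 ± 0.09 (adjusted p = 0.00301), CRELD2 by 0.96 ± 0.09 (adjusted p = 0.00375), the chaperone HYOU1 by 0.95 ± 0.10 (adjusted p = 0.0053) and calreticulin (CALR) by 0.49 ± 0.08 (adjusted p = 0.0236, not called in any of the 6 fits with an array left out, at most 0.0918 without control replicate 1). This list rose in the camera test (median 0.49, adjusted p = 1.02e-07, and adjusted p = 0.187 with an estimated correlation). Without replicate 3 of the hydrolysis product group 4 members rose. Of 19 genes of the ATF4 and integrated stress response list, 3 rose, 2 fell and 14 did not pass (3 and 5 adjusted over the list alone), and the list did not pass (median -0.34, camera adjusted p = 0.136). ATF3 rose by 1.56 ± 0.12 (adjusted p = 0.00198), the stress cytokine GDF15 by 1.01 ± 0.13 (adjusted p = 0.01) and DDIT3, which encodes CHOP, by 0.88 ± 0.16 (adjusted p = 0.0281). The serine synthesis enzyme PSPH fell by 1.04 ± 0.11 (adjusted p = 0.00516). GDF15 lost its call without control replicate 1 (adjusted p = 0.0572) and DDIT3 in 4 of 6 such fits (at most 0.102, without control replicate 1). The list passed, lower, without replicate 3 of the hydrolysis product group (adjusted p = 0.0211, with 3 members higher and 1 lower) and without control replicate 3 (adjusted p = 0.028).

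Of 14 NRF2 and oxidative stress genes, 4 rose and 10 did not pass (6 higher and 1 lower adjusted over the list alone). These were heme oxygenase HMOX1 (1.15 ± 0.12, adjusted p = 0.00544), the sulfiredoxin SRXN1 (0.86 ± 0.11, adjusted p = 0.01), thioredoxin reductase TXNRD1 (0.65 ± 0.09, adjusted p = 0.0103) and glutathione reductase GSR (0.50 ± 0.08, adjusted p = 0.0225). NRF2 list members had a median of 0.24 (camera adjusted p = 0.00235, and adjusted p = 0.158 with an estimated correlation). SRXN1 lost its call without control replicate 1 (adjusted p = 0.0564) and GSR in all 6 fits that left out an array (at most 0.0813, without control replicate 2).

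All 20 measured members of the type I interferon response list had log2 changes below 0, of which 16 were called. All 20 were lower when adjusted over the list alone. IFI44L fell by 3.40 ± 0.27 on the log2 scale, CXCL10, which recruits T cells, by 2.18 ± 0.19 (adjusted p = 0.00256), the apoptosis-linked XAF1 by 1.44 ± 0.10 (adjusted p = 0.00171) and the antiviral GTPase MX2 by 1.41 ± 0.11 (adjusted p = 0.00235). The interferon list fell in the camera test (median -0.78, adjusted p = 2.78e-18, and adjusted p = 0.133 with an estimated correlation). Without replicate 3 of the hydrolysis product group, 13 members were called.

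Of 20 measured NF-kB target cytokines and chemokines, 1 rose, 3 fell and 16 did not pass (2 and 5 adjusted over the list alone), and the list did not pass (median -0.16, camera adjusted p = 0.324). The monocyte chemokine CCL2 fell by 0.91 ± 0.12 (adjusted p = 0.0108), CCL5 by 0.62 ± 0.10 (adjusted p = 0.0212) and TNF by 0.45 ± 0.09 (adjusted p = 0.0331). CXCL5 rose by 1.33 ± 0.19 (adjusted p = 0.0136). TNF was called in none of the 6 fits with an array left out (at most 0.118, without control replicate 3) and in 2 of 3 further normalisations. CCL5 was called in 1 of those 6 fits (at most 0.0888, without control replicate 3). CXCL5 passed in 5 (0.0588 without control replicate 1). Of 20 toll-like receptor and inflammasome genes, 2 fell and adjusted over the list alone 2 rose and 5 fell. The called genes were TLR7 (-1.21 ± 0.20, adjusted p = 0.0209) and the DNA sensor AIM2 (-0.83 ± 0.14, adjusted p = 0.021). TLR7 lost its call without 2 of the arrays (at most 0.0832, without control replicate 2) and AIM2 without 4 (at most 0.0852, without control replicate 3). CD14 (-0.73 ± 0.16, adjusted p = 0.053) and MYD88 (-0.47 ± 0.13, adjusted p = 0.0933) did not pass, nor did the list (camera adjusted p = 0.494). The costimulatory molecules CD80 (-0.67 ± 0.11, adjusted p = 0.0236) and CD86 (-0.96 ± 0.18, adjusted p = 0.0302) fell, and the protease CTSS had a change of 0.03 ± 0.09. These 3 were the only antigen presentation genes measured here, too few for a list test. CD80 was called in none of the 6 fits with an array left out (at most 0.0753, without control replicate 1). CD86 was called in 1 of them (at most 0.109, without control replicate 2). Neither was called without replicate 3 of the hydrolysis product group.

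Of 29 measured cell cycle genes, 22 fell, 7 did not pass and all had log2 changes below 0, and all 29 were lower when adjusted over the list alone. Cyclin A2 (CCNA2) fell by 1.49 ± 0.12 and the ribonucleotide reductase subunit RRM2 by 1.49 ± 0.13 on the log2 scale (adjusted p = 0.00256 each), and the replicative helicase subunits MCM3 and MCM6 by 1.08 ± 0.09 and 1.11 ± 0.10 (adjusted p = 0.00256 each). The cell cycle list fell in the camera test (median -0.99, adjusted p = 9.83e-27, and adjusted p = 0.133 with an estimated correlation). Of its members, 19 were called without replicate 3 of the hydrolysis product group. Among markers of differentiation, MYB, a progenitor transcription factor, fell by 1.28 ± 0.12 (adjusted p = 0.00368), and of the other 8 measured markers of undifferentiated myeloid cells only SPN was called, at 0.45 ± 0.10 (adjusted p = 0.0491), with the same counts adjusted over the list alone. SPN was called under 1 of 3 further normalisations and in none of the fits with an array left out (at most 0.143, without control replicate 1). The granule protein genes PRTN3 (0.40 ± 0.16, adjusted p = 0.206) and CTSG (0.29 ± 0.20, adjusted p = 0.448) did not pass, nor did this list (camera adjusted p = 0.829). The mean level of PRTN3, 6.07, also lay under 6.28. Of 13 differentiated macrophage markers, 3 rose, the efferocytosis receptor MERTK (0.57 ± 0.10, adjusted p = 0.0236), the lipid receptor TREM2 (0.69 ± 0.12, adjusted p = 0.027) and GPNMB (0.50 ± 0.09, adjusted p = 0.0288). Adjusted over the list alone, 8 rose and 2 fell. That list's median was 0.35 (camera adjusted p = 0.000179, and adjusted p = 0.187 with an estimated correlation). The call ended among genes above the 75th percentile of level (median 0.30, adjusted p = 0.332) and was kept among genes at or above the median level (median 0.35, adjusted p = 0.00555). MERTK, TREM2 and GPNMB lost their calls in at least 4 of the 6 fits with an array left out (at most 0.102, for TREM2 without control replicate 1).

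**Figure D3:**
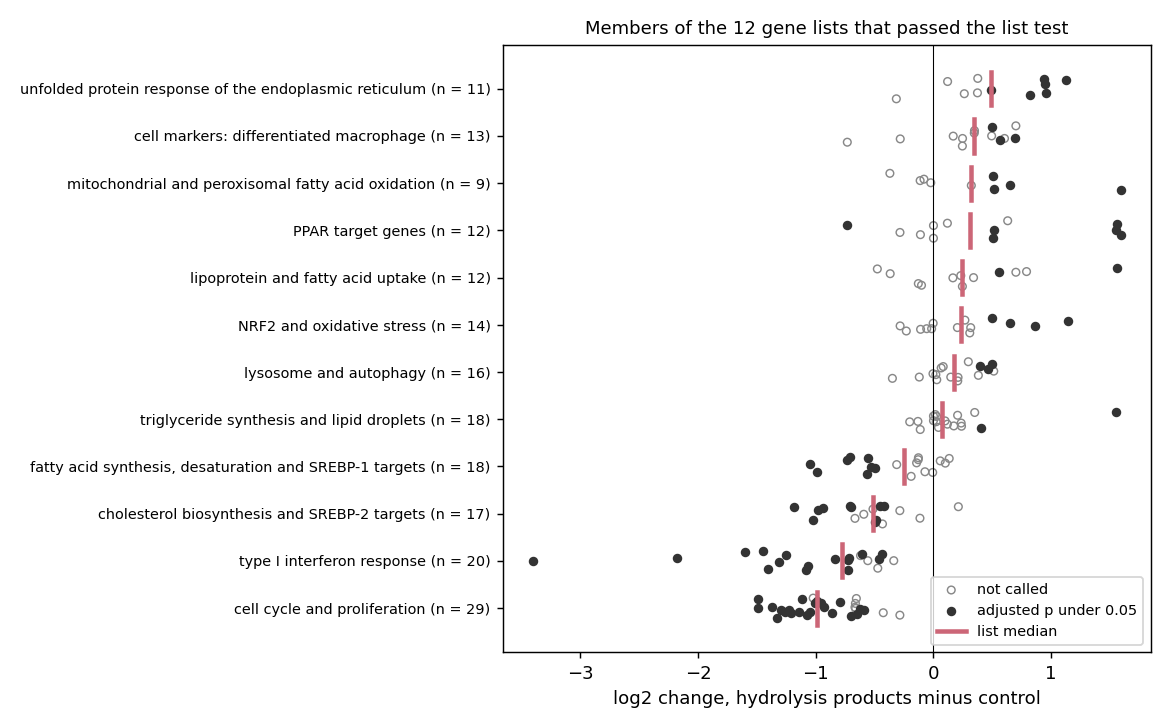
Log2 change (hydrolysis products minus control) of each measured member of the 12 gene lists with a camera adjusted p under 0.05, ordered by list median. Filled points are genes with adjusted p under 0.05, open points genes that did not pass, and bars list medians, from -0.99 for the cell cycle to 0.49 for the unfolded protein response.

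Of 16 matrix and adhesion genes, 3 rose, 4 fell and 9 did not pass (4 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.152). Without replicate 3 of the hydrolysis product group 1 adhesion gene rose and 4 fell. The collagenases MMP1 and MMP8 fell by 1.04 ± 0.12 (adjusted p = 0.00595) and 1.06 ± 0.12 (adjusted p = 0.0061) and MMP12 by 1.62 ± 0.25 (adjusted p = 0.0155). MMP19 rose by 0.87 ± 0.11 (adjusted p = 0.00743). MMP12 passed in 3 of the 6 fits with an array left out (at most 0.0775, without control replicate 2). Of 16 lysosome and autophagy genes, GPNMB, the protease CTSL (0.47 ± 0.10, adjusted p = 0.0441) and the hexosaminidase HEXA (0.40 ± 0.08, adjusted p = 0.0454) rose, with LAMP1 at 0.38 ± 0.09 (adjusted p = 0.0614). The lysosome list had a median of 0.18 (camera adjusted p = 0.00162, and adjusted p = 0.146 with an estimated correlation). Adjusted over the list alone, 5 members rose and 1 fell. CTSL and HEXA were called in none of the 6 fits with an array left out (at most 0.136 without control replicate 1 and 0.151 without control replicate 3). A total of 1 member of the list was called without replicate 3 of the hydrolysis product group, where its median was 0.11 (adjusted p = 0.00663).

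Of 18 immediate early genes, ATF3 and JUN (0.87 ± 0.13, adjusted p = 0.015) rose and the phosphatase DUSP2 fell by 1.20 ± 0.15 (adjusted p = 0.00743). FOS was at 0.47 ± 0.12 (adjusted p = 0.0811). The immediate early list did not pass (camera adjusted p = 0.468, with 3 higher and 2 lower adjusted over the list alone, and 2 and 2 without replicate 3 of the hydrolysis product group). JUN passed in 4 of the 6 fits with an array left out (at most 0.0717, without control replicate 2). No member passed, adjusted over all genes, among the lists of alternative activation markers (15 measured, PPARG at 0.36 ± 0.09 with adjusted p = 0.0649), metallothioneins (10), glycolysis and hypoxia (15), apoptosis and p53 targets (14, BCL2 at -0.42 ± 0.09 with adjusted p = 0.0551), insulin, PI3K and FOXO signalling (16, INSR at 0.30 ± 0.09 with adjusted p = 0.132), nuclear-encoded oxidative phosphorylation (9) or ribosomal proteins (21, median -0.02). Their camera adjusted p-values were 0.121, 0.97, 0.97, 0.121, 0.97, 0.642 and 0.829. Adjusted over the list alone, 2 apoptosis genes were lower and no others passed. The apoptosis list passed without control replicate 2 (adjusted p = 0.0471) and the alternative activation list without hydrolysis product replicate 2 (adjusted p = 0.0462). No marker of kidney epithelial cells (12 measured), lymphoid cells (10) or erythroid cells and platelets (4) passed, with list medians of -0.02, 0.04 and 0.07. The list median, mean and test differed in sign for the LXR, insulin signalling and undifferentiated myeloid lists, none of which passed.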

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

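In the fit on all 53617 rows, 312 of the 37519 rows without a gene symbol here passed an adjusted p under 0.05 (206 higher and 106 lower), a signal in data that the gene comparisons do not use. What these rows measure is not analysed here.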

How the results depend on the processing

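Direction was kept for each of the 74 called named genes and 12 called lists in every alternative that gave them a value. The 2 level limits dropped some of these genes and left 26 and 21 lists tested, without the interferon list above the 75th percentile. There the medians of the PPAR, fatty acid synthesis and uptake lists were 1.03, -0.53 and 0.45. Among genes at or above the median level, the PPAR and fatty acid synthesis medians were 0.51 and -0.49. Gene counts moved with the setting. Against 270 higher and 421 lower, a replicate block gave 126 and 183 (110 and 175 of them shared), eBayes with trend and robust variances 570 and 710 (261 and 402 shared), and genes at or above the median level 606 and 674. Genes above the 75th percentile of level gave 455 higher and 523 lower (123 and 189 shared). The fit on all rows, with more rows in the adjustment, counts rows and not genes and gave 284 higher and 238 lower, of which only 78 and 132 were named rows. A further 1.5-fold limit gave 167 and 257, and an adjusted p under 0.1 gave 544 and 671. Leaving out 1 array gave 58 to 143 higher and 117 to 290 lower, with fewer arrays in the fit, the fewest without control replicate 1 and the most without hydrolysis product replicate 3. The cause of the other differences was not tested. The labels do not say whether same-numbered samples were run together. Deviations of same-numbered samples from their group means correlated at 0.00936, 0.00955 and 0.0267. Those of differently numbered samples correlated between -0.0313 and 0.0193. Values this weak neither show nor exclude pairing. Not every array correlated best with its own number (control replicate 1 reached 0.0193 with replicate 2). With the block 12 lists passed. The number of lists past the threshold was 1 with an estimated correlation, and otherwise 10 to 15, the 15 with fry, which added the apoptosis, adhesion and toll-like receptor lists. Adjusted over 35 together with the groups chosen later, the cholesterol list had adjusted p = 0.0539 with an estimated correlation and no list passed that test. Array weights, the 3 further normalisations, the mean of a gene's rows and the removal of small RNA genes (chosen after seeing the data) kept both gene counts within 1.5 times. The median change of all genes moved between -0.03 and 0.03 over the normalisations. Over 16 alternatives, 144 of 2004 values of the 130 named genes, called or not, lost their call and 61 gained one. Only the 74 called genes could lose a call. Of these, 45 were called in all 6 fits that left out 1 array and 29 in fewer. The arrays carry no detection call, so a dim level, such as 4.23 for IFI44L with hydrolysis products, cannot be told from background here. Changes of 0.5 on the log2 scale were mostly missed in the simulation. It held fewer changed genes than were called here, so its recovery rates need not hold for these data.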

Other observations

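The gene groups in these first 2 paragraphs, the genes named in them outside the fixed rule, VTRNA1-1, RMRP, RPPH1, SNAR-I and AZU1 below, and the floor reference were chosen after results had been seen, so their tests are not independent evidence. Adjusted p-values of these groups are over the 7 groups alone. Small Cajal body RNAs, which guide modification of spliceosomal RNAs, were higher with hydrolysis products in each of 23 named genes, 14 of them called in the limma fit. SCARNA8 went from 8.80 ± 0.29 to 10.96 ± 0.13 (SD, n = 3 each), SCARNA4 changed by 2.04 ± 0.11 (adjusted p = 0.0016) and SCARNA3 by 1.96 ± 0.14 (adjusted p = 0.00171). The median was 0.96 on the log2 scale, and the group passed camera (adjusted p = 7.27e-22, and adjusted p = 0.0437 with an estimated correlation). Adjusted over 35, together with the 28 fixed lists, that call with an estimated correlation was lost (adjusted p = 0.109). Of 15 measured heat shock protein genes 3 rose, HSPA1A, HSPA1B and the co-chaperone BAG3 (1.20 ± 0.20, adjusted p = 0.0211). HSPA6 (1.29 ± 0.34, adjusted p = 0.0849, control mean under 6.28), CHORDC1 (0.68 ± 0.17, adjusted p = 0.0757), HSPH1 (0.11 ± 0.08), HSPA4 (0.03 ± 0.08) and HSPD1 (0.21 ± 0.11) did not pass. All 15 changes were above 0, and 5 genes rose when adjusted over the group alone. The group's camera adjusted p was 2.33e-06, and adjusted p = 0.181 with an estimated correlation.

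Of 17 DNA replication and repair genes 14 fell, with a median of -1.07 (camera adjusted p = 9.79e-19, and adjusted p = 0.0814 with an estimated correlation). The histone chaperone ASF1B fell by 1.21 ± 0.09 (adjusted p = 0.00195) and the helicase MCM8 by 1.21 ± 0.12 (adjusted p = 0.00375). Of 11 genes known for induction by interferon gamma 3 fell, GBP5 (by 1.08 ± 0.09, adjusted p = 0.00256), CXCL10 and CXCL11, and IRF1 (-0.15 ± 0.09) did not pass. CXCL11 had both group means under 6.28, the floor reference explained below, and CXCL10, GBP5 and ASF1B had 1, so the sizes of these falls are uncertain. That group had a median of -0.32 (camera adjusted p = 4.68e-05, and adjusted p = 0.0814 with an estimated correlation). Of 18 glutathione and detoxification enzymes 1 rose, MGST1 (adjusted p = 0.00681, both group means under 6.28), with a group median of 0.21 (camera adjusted p = 3.35e-05, and adjusted p = 0.108 with an estimated correlation). With only genes above 6.28 in both groups, the medians were 0.09 over 8 detoxification enzymes, -0.27 over 5 interferon gamma genes, -0.86 over 4 replication genes, 0.18 over 12 heat shock genes and 1.13 over 15 small Cajal body RNAs. This limit also drops genes that crossed 6.28 between the groups, such as CXCL10, GBP5 and ASF1B. These medians therefore leave out some of the larger changes. The microRNA genes, 1072 in all, had a median of 0.03, with 11 higher and 12 lower, and did not pass camera (adjusted p = 0.105).

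The real grouping called 691 genes, and the highest of the other 9 splits of the 6 arrays into 3 and 3 called 0, so 1 of 10 splits gave as many. These splits are too few for a share under 0.05. Each of the other 9 also mixes the groups, so differences between the groups widen the spread within its sides and lower its count. The 0 calls there are therefore no support for the 691.

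The higher small Cajal body RNAs may have a technical source. The tables argue against 1 array deciding the rise, since the median was 0.91 or more whichever array was left out. The median was also 1.01 or more under 3 further normalisations. These were applied to values that the authors had already quantile-normalised, so they do not test the authors' normalisation. A higher recovery or labelling of small RNA as a class would raise other small structured RNAs too, and their median over 15 genes was 0.056, with a mean of 0.24 and a camera call in the upward direction (adjusted p = 0.0336, or 0.0559 over 35, and adjusted p = 0.219 with an estimated correlation). Of the 15, 3 were called higher and 1 lower, and the largest change was in VTRNA1-1 (1.76 ± 0.25, adjusted p = 0.0119, both group means under 6.28). Many of the 15 are SNAR genes of a single family, so the bootstrap does not draw on independent genes. The median's bootstrap interval, from -0.084 to 0.54, reaches past the scaRNA lower quartile of 0.39, but the 7 of these genes above 6.28 in both groups, a limit added later, had a median of -0.077 and an interval ending at 0.47, just under the lower quartile of 0.49 of the 15 scaRNA genes so limited. That narrow margin over 7 genes, of which RMRP (0.47) and RPPH1 (0.54) rose and SNAR-I (-0.53) fell, does not decide, so recovery of small RNA and an effect of the hydrolysis products cannot be told apart.

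The lower cell cycle transcripts could come from a smaller share of undifferentiated dividing cells or from less division among macrophages. The tables argue against 1 array deciding the fall, since the median was -0.90 or lower in each of the 6 fits that left out 1. MYB, which the bound below leaves out, fell by 1.28 ± 0.12, with 1 group mean under 6.28. The differentiated macrophage list rose (median 0.35, camera adjusted p = 0.000179, and adjusted p = 0.187 with an estimated correlation). Both could go with a smaller share of undifferentiated cells, but neither decides. The undifferentiated myeloid markers other than MYB above the median level, AZU1, PRTN3 and SPN, had a median change of 0.40, which met the bound set in advance against a smaller share (above the upper quartile of the cell cycle genes, -0.66). That bound is not relied on, because a floor reference chosen after this value was seen put only 1 of the 3 markers above 6.28, the 95th percentile of 85 keratin-associated protein, beta-defensin and taste receptor genes, with AZU1 at 6.19 and PRTN3 at 6.07. The reference genes had a median level of 3.82, so AZU1 and PRTN3 lay between their median and their 95th percentile. Only 1 marker above 6.28 is too few to decide, so the 2 explanations cannot be told apart.

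The lower interferon-induced genes were set against a general fall of inflammatory activation, read from 1 list of NF-kB target cytokines and chemokines. Of its 29 members 20 were measured, and their values argue against such a fall as the whole cause, for these members only. The inflammatory list had a median of -0.16 (bootstrap interval -0.34 to 0.12, and median -0.07 without control replicate 3, further from the interferon list), above the interferon list's upper quartile of -0.60, and did not pass camera (adjusted p = 0.324). Outside this list, CCL1, CCL19, IL33, CD80, CD86, TLR7 and AIM2 fell and IL24 rose. Fry called the toll-like receptor list lower (adjusted p = 0.0148), which camera did not (adjusted p = 0.494), with 8 of its 20 changes above 0. A fall of activation beyond the inflammatory list is therefore not excluded. A single array deciding the fall of the interferon list was also argued against (median -0.72 or lower in each of 6 fits). Also open and untested is whether hydrolysis products lowered an interferon response or the control medium raised it. This stays open because no macrophages without lipoproteins or medium are among these samples. The groups also differ in the source of the medium, LPL-expressing or control cells. For every change reported here, effects of LPL protein or other medium components cannot be told apart from those of the hydrolysis products.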
